A study of Danio rerio with 11 samples.

How the data were processed

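RNA was measured in 11 libraries made from tails of zebrafish embryos at 24 hours post fertilisation, each library from a pool of 5 tails, per the labels. The labels give a stranded total RNA library kit with removal of ribosomal RNA, and paired reads of 150 bases. The submitters' notes list cutadapt 1.16, STAR 2.7.2c, DESeq2 1.22.2 and the genome build GRCz11, with no role or order for any of them. The tool that counted reads per gene and the annotation release were not given in the sources used here.

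The authors deposited 1 table of raw counts, whole numbers per Ensembl gene identifier and library, with no normalization per the file headers and the values. All of its per-sample columns were used. The authors also deposited 6 tables of comparisons between groups, whose fold changes are on the log2 scale per the file headers. The same deposited tables hold the authors' adjusted p-value for each gene, blank for some genes. Their design and any shrinkage of fold changes were not given in the sources used here, and 4 of these tables match a comparison made below, so they were used only as counts set beside it. The name of 1 table gives line 23095 with an extra digit. It was read as the wildtypes of that line against those of line 36433, since its fold changes correlated with those found here (Pearson's r = 0.853 across genes) and had the same sign in 82 of 82 called genes.

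The count table held 23617 gene identifiers, of which 21998 had a symbol in the gene name table used here. Symbols are printed as that table gives them. For 11492 identifiers the symbol was in upper case, the style of human genes, and 3309 identifiers shared their symbol with another identifier. Reads can be shared between near-identical copies, so values of genes with a shared symbol are uncertain. No genome sequence was used. The order of genes along a chromosome came from RefSeq on a later zebrafish assembly than the build the labels name, and served only to find neighbours of kdm1a.

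Libraries were grouped by line and genotype as the labels state, which gave 4 groups. Counts were scaled with TMM factors, genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), and 20886 genes were tested. Differences were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest), a quasi-likelihood F-test that is two-sided, in 1 model of the 4 group means over all 11 libraries with 7 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over all tested genes, and a gene was called at an adjusted p under 0.05. Contrasts were mutant against wildtype within each line, their average over both lines, their difference (line 23095 minus line 36433), wildtype against wildtype and mutant against mutant (both line 23095 minus line 36433). CPM are counts scaled to library size after TMM (edgeR's cpm), given as mean and SD over the libraries of a group. Standard errors of log2 fold changes were derived from the F statistic. These p-values measure only the spread between the pools sequenced, and nothing in the labels says whether the pools came from separate clutches.

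Gene lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, and adjusted over the 26 of 27 lists that had at least 5 tested members. Camera with an estimated correlation and fry were the alternatives. The 825 list symbols were matched to 704 genes, 565 by symbol, 6 by a RefSeq synonym and 133 by the symbol of the human ortholog. The ortholog step was added after the gene tables had been seen and before any list was tested, except that the match of gfi1ab to GFI1 was made after the value of GFI1 had been seen. Some genes stand in 2 lists, so these lists are not independent. Among them, GFI1, gfi1aa and GFI1B are in those of blood stem cells and Lsd1 partners, and LMO2 and TAL1 in those of blood stem cells and endothelium.

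The groups, the comparisons, the tests, the gene lists, the alternatives and the rule for which genes are named were chosen before the data were examined. The rule named kdm1a and, in each comparison of mutants with wildtypes, up to 10 genes with the largest rise and 10 with the largest fall among called genes with a mean log2 CPM of at least 1, a symbol that is not a clone name, and every mutant library beyond every wildtype library of its line. It added up to 4 members of each list with the smallest p, and in the comparisons across lines up to 5 genes per direction. Other genes named below were chosen after their values were seen.

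The alternatives were DESeq2's size factors, library totals alone, no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. A newer form of edgeR's quasi-likelihood method, and list members matched by symbol only, were added after the data had been seen. Where leaving out a library left a group with 1 library, that library was assumed to vary like those of the other groups.

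The pipeline was tested on simulated counts in which 200 genes were changed, all with a mean log2 CPM of at least 1, so the shares recovered do not cover genes below that level. At a fold of 2, 54.7% of changed genes were recovered within line 36433, 43.8% within line 23095, 79.7% in the average and 12.5% in the difference between lines. At a fold of 4, the shares were 95.4%, 92.3%, 100% and 84.6%, and at a fold of 8 they were 98.6%, 98.6%, 100% and 93.0%. False calls numbered 9, 11, 13 and 7 among 20788, 20775, 20800 and 20808 genes. In the simulated list test, a list of 30 genes raised by a fold of 1.5 was detected, and 4 of 200 lists without a change fell under the unadjusted threshold of 0.05. Simulated genes varied independently, so correlation between genes was not tested.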

Results

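The data are total RNA counts from the tails, behind the yolk sac, of zebrafish embryos carrying mutations in lsd1 and of their wildtype siblings. Lsd1, whose gene is kdm1a (KDM1A in the symbol table, ENSDARG00000060679), is a histone lysine demethylase that acts mostly as a repressor of transcription with partner proteins. Line 36433 had 3 mutant and 3 wildtype libraries, and line 23095 had 3 mutant and 2 wildtype libraries. The kind of lesion in each line was not given in the labels. Total counts were 12199605, 15802611 and 13537829 in the mutants of line 36433, and 14785707, 15234507 and 16649352 in its wildtypes. They were 15799984, 8204459 and 16535501 in the mutants of line 23095 (replicates 1, 2 and 4), and 17195875 and 15329063 in its wildtypes. The 10 genes with most counts took 19.2% and 17.4% of the counts in the 23095 wildtypes, against 13.3% to 15.0% in the other 9 libraries.

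Transcripts of kdm1a fell in the mutants of line 36433, and no difference was called in the mutants of line 23095. In line 36433, the level was 36.9, 34.2 and 34.8 CPM in the mutants and 162, 155 and 135 CPM in the wildtypes, a log2 fold change of -2.10 (standard error 0.15, adjusted p = 6.93e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg). In line 23095, it was 130, 170 and 130 CPM in the mutants and 124 and 142 CPM in the wildtypes, a log2 fold change of 0.11 (standard error 0.16, adjusted p = 0.781). The mutant effects differed between the lines by 2.2 on the log2 scale (standard error 0.22, adjusted p = 0.00407), although this difference was not called without 23095 wildtype replicate 1 (adjusted p = 0.12). Without 23095 mutant replicate 2, the log2 fold change in line 23095 was -0.03.

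**Figure D1:**
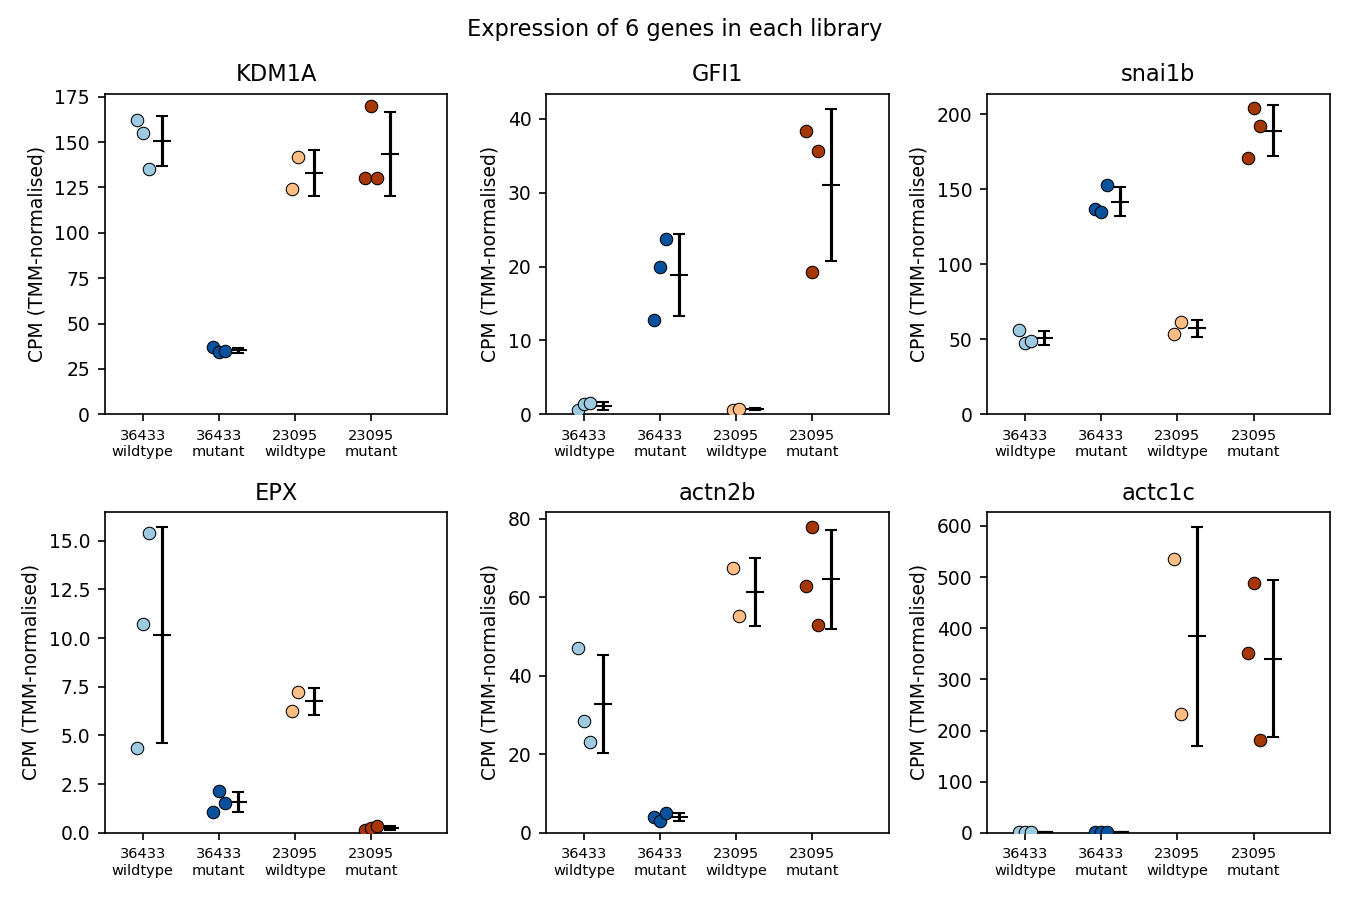
Level of 6 genes in CPM in each library, by line and genotype; points are libraries, and the bar beside them is the group's mean with its SD. KDM1A lies at 34.2 to 36.9 CPM in the 36433 mutants and at 124 CPM or more in the other libraries, whereas GFI1 and snai1b lie higher in the mutants of both lines.

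The comparison within line 36433 asked which transcripts differed between mutant tails and those of wildtype siblings. The largest rise was that of GFI1 (ENSDARG00000044457), a zinc-finger repressor of blood cells that works with Lsd1, from 1.11 ± 0.521 to 18.8 ± 5.56 CPM (SD, n = 3 each), a log2 fold change of 4.08 (standard error 0.38). Its paralog gfi1aa rose by 3.10 on the log2 scale (standard error 0.45). Of the snail genes, repressors that share with GFI1 the SNAG domain that binds Lsd1, snai3 rose by 2.35 (standard error 0.20), snai1b by 1.48 (standard error 0.14) and snai1a by 1.14 (standard error 0.19). Transcripts of vwf, the clotting factor made in vessel walls, rose by 3.66, those of the ETS-family gene spi2 by 3.03, and those of the lymphoid adaptor SASH3 by 2.46. The largest falls were in gfral (fell by 4.33), the mucin muc5.1 (fell by 3.22), the muscle actin crosslinker actn2b (fell by 3.05, standard error 0.28), the parvalbumin gene pvalb8 (fell by 2.79) and the granulocyte peroxidase EPX (fell by 2.66). Further named genes were rasl10a, RASGRP2, SLC16A12 and gmip, which rose by 1.96 to 2.21, and msmp2, which fell by 1.64.

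In all, 25 genes rose and 10 fell in line 36433 of 20886 tested (edgeR's quasi-likelihood test with Benjamini-Hochberg), and 1410 had an unadjusted p under 0.05 where chance gives 1044. The mutant and wildtype libraries did not overlap in 13.5% of all tested genes, where chance gives 10%; the 35 were among these, which their selection by the same difference favours. The blood stem and progenitor list shifted up (median log2 fold change 0.61, adjusted p = 4e-08; adjusted p = 0.45 with an estimated correlation): 2 of 15 members rose over all genes, GFI1 and gfi1aa, and 7 rose adjusted over the list alone. GFI1 was matched to this list and to that of Lsd1 partners after its value had been seen, so it is no independent support for either. The endothelial list shifted up (median 0.28, adjusted p = 1e-05; adjusted p = 0.55 with an estimated correlation), with no member called over all genes and 3 higher and 1 lower adjusted over the list alone. The myeloid list shifted down (median -0.65, adjusted p = 2.4e-05; adjusted p = 0.55 with an estimated correlation), with none of 26 members called over all genes and 1 higher and 7 lower adjusted over the list alone. The lists for cell cycle (-0.16), yolk syncytial layer and liver (-0.44), epidermis and periderm (-0.27), neural crest and pigment (-0.36), erythroid cells (-0.29) and neuronal genes (-0.19) also had lower medians that passed the test, and the list of Lsd1 partners a higher one (0.16). With an estimated correlation these last 7 gave adjusted p-values of 0.55 to 0.72. Leaving out wildtype replicate 2 ended the list calls of epidermis, erythroid cells, yolk and Lsd1 partners (adjusted p = 0.89, 0.13, 0.074 and 0.074), wildtype replicate 1 those of erythroid cells and neuronal genes (0.39 and 0.96), and wildtype replicate 3 those of epidermis and Lsd1 partners (0.094 and 0.08). Leaving out mutant replicate 1, 2 or 3 ended that of Lsd1 partners (0.059), erythroid cells (0.12) or neuronal genes (0.073). Without mutant replicate 1, 2 or 3 the count of genes was 17, 15 or 12, and without wildtype replicate 1, 2 or 3 it was 64, 13 or 19. KDM1A, GFI1, snai3, snai1b, vwf, spi2 and actn2b kept their calls in each of these 6 fits, whereas EPX, muc5.1 and pvalb8 lost theirs in 5 (adjusted p up to 0.187, 0.222 and 0.255), gfi1aa in 3 (up to 0.11), and SASH3 and gfral in 2 (up to 0.0732 and 0.0536). The calls of rasl10a, RASGRP2, SLC16A12, gmip and msmp2 were lost in 3 to 6.

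The same question in line 23095 gave more called genes in the main fit. This excess was absent in a fit of only the groups compared (6 against 32 in line 36433). With the replicate number as a block it was small (33 against 31). GFI1 rose from 0.657 ± 0.126 (SD, n = 2) to 31.1 ± 10.3 CPM (SD, n = 3), a log2 fold change of 5.56 (standard error 0.49). SASH3 rose by 3.35, vwf by 2.85, gfi1aa by 2.63, snai3 by 2.54 (standard error 0.23) and snai1b by 1.72 (standard error 0.16). Of genes known from the presomitic mesoderm, the tissue that forms the somites, tbx6 rose by 3.49 (standard error 0.76), her7 by 2.81 and mespaa by 2.40. EPX fell by 4.78 (standard error 0.58), and pvalb8 by 3.98. XIRP2 fell by 4.62 (standard error 0.64; 2 identifiers share the symbol), SLC25A4 fell by 3.58, and pvalb1 fell by 3.46; of these, only pvalb1 stands in the muscle list. Other named falls were those of tcnbb (-4.23), IGSF10 (-4.20), BSCL2 (-3.84), muc5.1 (-3.45) and the macrophage gene MFAP4 (-3.59), whose symbol 5 identifiers share. GFI1, snai3, snai1b and EPX kept their calls in each of the 5 fits that left out 1 library. The other 15 genes named in this paragraph lost theirs without wildtype replicate 1 (adjusted p from 0.119 for XIRP2 to 0.428 for tbx6). All of these but SASH3, XIRP2 and IGSF10 also lost theirs without mutant replicate 4 (0.0602 to 0.118), and 9 of them (tbx6, her7, mespaa, vwf, gfi1aa, SLC25A4, pvalb1, tcnbb and BSCL2) without wildtype replicate 2 (0.0602 to 0.145). The calls of tbx6 and pvalb1 were lost as well without mutant replicate 2 (0.0543 and 0.0724), and that of SLC25A4 without mutant replicate 1 (0.0596), where BSCL2 fell by 7.21.

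In line 23095, 145 genes rose and 195 fell (edgeR's quasi-likelihood test with Benjamini-Hochberg), and 3516 had an unadjusted p under 0.05. The groups did not overlap in 33.8% of all tested genes, where chance gives 20%; the 340, selected by the same difference, were among these. The tailbud and presomitic mesoderm list shifted up (median log2 fold change 0.75, adjusted p = 6.2e-09; adjusted p = 0.18 with an estimated correlation), with 6 of 38 members higher over all genes, and 14 higher and 2 lower adjusted over the list alone. The skeletal muscle list shifted down (median -0.70, adjusted p = 3.1e-08; adjusted p = 0.45 with an estimated correlation), with 4 of 42 members lower (mybpc2b, pvalb1, TNNT3, trdn), and 2 higher and 22 lower adjusted over the list alone. These 4 lost their calls without wildtype replicate 1 (adjusted p = 0.309, 0.309, 0.309 and 0.338), mutant replicate 4 (0.0597, 0.0763, 0.0855 and 0.0937) and wildtype replicate 2 (0.0858, 0.0956, 0.103 and 0.147), and pvalb1 and TNNT3 also without mutant replicate 2 (0.0724 and 0.0746). Before any mutant is considered, the 23095 wildtypes lay apart from the 36433 wildtypes on both lists, by -0.70 for tailbud and 0.68 for muscle (adjusted p = 3.6e-11 and 4.5e-12; adjusted p = 0.34 and 0.61 with an estimated correlation), with no member of either called over all genes.

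The myeloid list shifted down in line 23095 (median -1.42, adjusted p = 6.1e-08; adjusted p = 0.18 with an estimated correlation), with 6 of 26 members lower over all genes and 2 higher and 14 lower adjusted over the list alone. Of the 6, fcer1gl lost its call in 4 of 5 fits that left out 1 library, LCP1 in 3 and the MFAP4 copy ENSDARG00000088745 in 2. The neural crest and pigment list shifted down (median -0.79, adjusted p = 6.7e-08; adjusted p = 0.18 with an estimated correlation): 9 members fell over all genes, among them the pigment genes pnp4a (fell by 2.55) and XDH (fell by 2.59), while snai1b, snai2 and FOXD3 rose. The calls of pnp4a, XDH and snai2 were lost without mutant replicate 4 (adjusted p = 0.0597, 0.0763 and 0.0907) and wildtype replicate 1 (0.204, 0.273 and 0.315), and those of XDH and snai2 without wildtype replicate 2 (0.0631 and 0.103). The blood stem list (median 1.03; 4 of 15 rose over all genes, 10 adjusted over the list alone) and the endothelial list (median 0.47; 6 rose and 2 fell of 37, 18 and 2 adjusted over the list alone) shifted up, each with an adjusted p = 0.18 with an estimated correlation. Of their called members, MYB, tek, SOX7 and pecam1a lost their calls in 4 of 5 fits that left out 1 library, gfi1aa in 3 and LMO2 in 2. GFI1, matched to the blood stem list after its value had been seen, kept its call. The list of Lsd1 partners (0.35), hox genes (0.21) and cilia (0.21) had higher medians, and yolk (-0.78), ionocytes (-0.65), epidermis (-0.27) and neuronal genes (-0.21) lower ones, that passed the test and did not with an estimated correlation (adjusted p = 0.18 to 0.76). Of these, hox genes, cilia, ionocytes, epidermis and neuronal genes lost their calls without wildtype replicate 1 (adjusted p = 0.34, 0.12, 0.1, 0.21 and 0.13), and hox genes, cilia, epidermis and neuronal genes without mutant replicate 1 (0.14, 0.21, 0.056 and 0.066). Hox genes, cilia and neuronal genes lost theirs without mutant replicate 4 (0.64, 0.18 and 0.19), epidermis without mutant replicate 2 (0.19) and cilia without wildtype replicate 2 (0.068). The count of 340 genes fell to 24 without mutant replicate 4, to 4 without wildtype replicate 1 and to 89 without wildtype replicate 2, and was 6 when only these 5 libraries were fitted. With library totals alone, which moved the median of all genes by 0.124 on the log2 scale, 207 genes rose and 162 fell, so that the share of rises was 56.1% rather than 42.6%.

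The lines were then compared for shared changes. Their within-line comparisons share no library, but both took each gene's spread from 1 model over all 11 libraries. The 2 lists of calls are therefore not fully independent. The Fisher's tests below allow neither for this nor for correlation between genes. Of the called genes, 18 rose in both lines, where independent lists would share 0.174 (one-sided Fisher's exact test, p = 2.17e-34). They included GFI1, gfi1aa, snai1a, snai1b, snai3, vwf, SASH3, RASGRP2, SMOC1 and OAT. A further 6 fell in both, where 0.0934 would be shared (one-sided Fisher's exact test, p = 1.25e-10), among them EPX, gfral, muc5.1 and pvalb8. Across genes, which are not independent replicates, Pearson's r between the lines' log2 fold changes was 0.334 over all 20886, 0.872 over the 35 called in line 36433 and 0.679 over the 340 called in line 23095. The direction was the same for 32 of the 35 and for 284 of the 340. The median size of the effect in line 23095 was 0.847 times that in line 36433 over the 35, and 3.63 times over the 340, and each group was chosen for large effects in its own line. Without 36433 wildtype replicate 1, 36 genes were shared, and without 23095 wildtype replicate 1 only 4; the other counts beyond 1.5-fold of 24 were 8 to 12, without 23095 mutant replicate 4, 23095 wildtype replicate 2, any 36433 mutant or 36433 wildtype replicate 2 or 3.

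**Figure D2:**
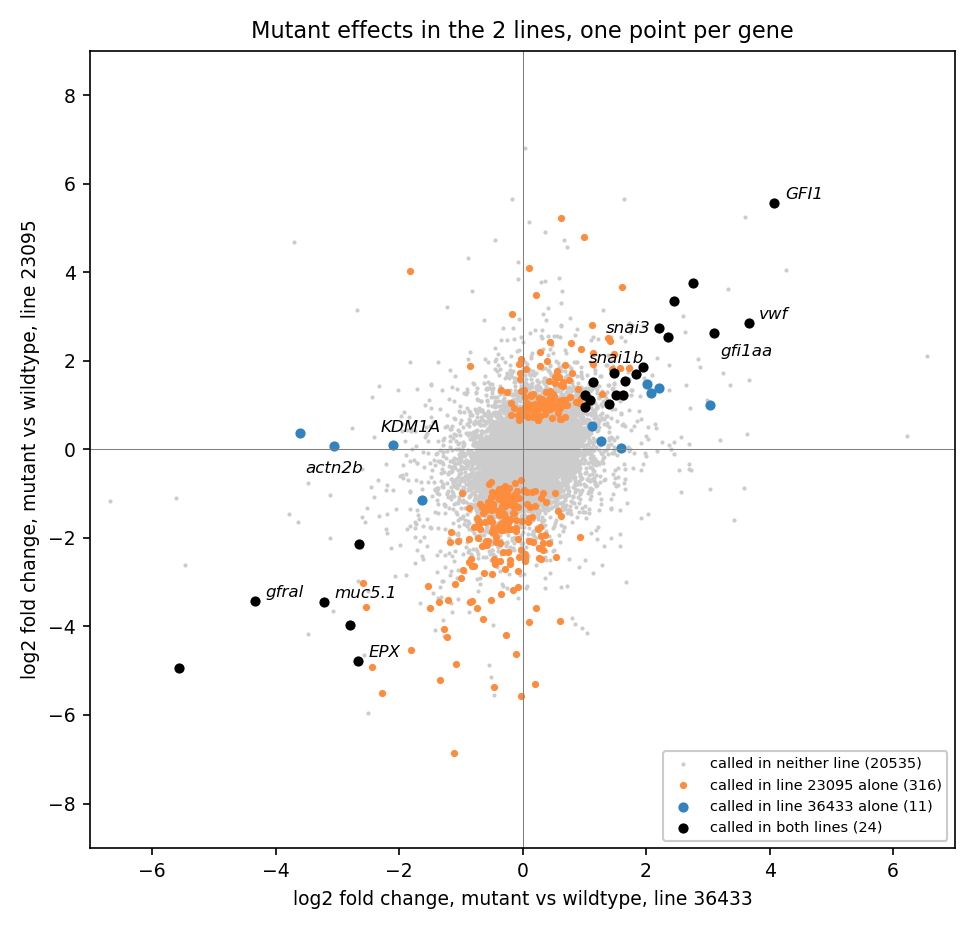
Log2 fold change of mutant against wildtype in line 23095 (y) against that in line 36433 (x), one point per tested gene, coloured by where the gene was called; 1 gene lies outside the axes. The 24 genes called in both lines lie in the upper right and lower left, and KDM1A and actn2b lie near 0 on the y axis.

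Averaged over both lines, which is the comparison the series title names, 271 genes rose and 215 fell (edgeR's quasi-likelihood test with Benjamini-Hochberg), with 3634 at an unadjusted p under 0.05. GFI1 rose by 4.82 on the log2 scale (standard error 0.31, adjusted p = 7e-06), vwf by 3.26, SASH3 by 2.90, gfi1aa by 2.87, RASGRP2 by 2.48 and snai3 by 2.44. The rise of spi2 was 2.02, and spi2 was not among the genes called in both lines. The snail genes snai1b, snai1a and snai2 rose by 1.60 (standard error 0.10), 1.33 (standard error 0.15) and 0.97 (standard error 0.13). Transcripts of gfral fell by 3.88, those of EPX by 3.72 (standard error 0.36, adjusted p = 0.000303), those of pvalb8 by 3.38 and those of muc5.1 by 3.34. HBE1, an embryonic globin, rose by 2.12, but 6 identifiers share its symbol and its value is uncertain. The mutant and wildtype libraries did not overlap in either line, with the same direction in both, in 4.02% of all tested genes, where chance gives 1%; 306 of the 486, selected by the same difference, were among these.

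Blood genes moved in opposite directions in this average. Of 15 blood stem and progenitor genes 7 rose over all genes and 9 adjusted over the list alone, with none lower (median log2 fold change 0.82, adjusted p = 7.2e-11; adjusted p = 0.2 with an estimated correlation). Among them were RUNX1 (rose by 1.71), GFI1B (rose by 1.72), IKZF1 (rose by 1.43) and LMO2 (rose by 1.09), all known regulators of early blood cells. GFI1, also among the 7, was matched to the list after its value had been seen. Of 26 myeloid genes 9 fell and 1 rose over all genes, and 15 fell and 3 rose adjusted over the list alone (median -1.06, adjusted p = 2.3e-08; adjusted p = 0.2 with an estimated correlation). The falls included the leukocyte genes CORO1A (fell by 1.70), LCP1 (fell by 1.56), ptprc (fell by 2.31) and lyz (fell by 3.60), and the rise was that of CSF3R, a receptor for granulocyte growth factor (1.24). Of 37 endothelial genes 8 rose, among them FLI1 (rose by 0.69), and plvapb fell by 0.98 (median 0.44, adjusted p = 3.2e-09; adjusted p = 0.2 with an estimated correlation; 19 rose and 2 fell adjusted over the list alone). The erythroid list did not pass the test (median -0.05, adjusted p = 0.8), with tspo lower (a call lost in 5 of 11 fits that left out 1 library). LMO2, RUNX1, CORO1A, LCP1, FLI1 and plvapb lost their calls without 23095 wildtype replicate 1 (adjusted p = 0.0711, 0.0855, 0.063, 0.0627, 0.0836 and 0.0634), and GFI1B lost its call in 4 of the 11 fits.

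Pigment genes fell in the average while snail genes of the same list rose. Of 33 neural crest and pigment genes 11 fell and 2 rose over all genes, and 21 fell and 3 rose adjusted over the list alone (median -0.62, adjusted p = 1e-07; adjusted p = 0.2 with an estimated correlation). The falls included pnp4a of the iridophores (fell by 1.71, standard error 0.25) and MLPH, which serves melanosome transport (fell by 2.18). The rises were snai1b and snai2. In line 36433, 26 of the 33 had a negative sign (median -0.36), but no member was called lower over all genes or adjusted over the list alone. In line 23095, 9 and 20 were, so the called falls rest largely on that line. Of 38 tailbud genes 3 rose, her7, mespaa and tbx16 (median 0.34, adjusted p = 1.5e-06; adjusted p = 0.26 with an estimated correlation; 12 rose and 1 fell adjusted over the list alone). In line 36433 the medians of the tailbud and skeletal muscle lists were 0.06 and 0.01, and neither passed camera (adjusted p = 0.51 and 0.32). The averages of these 2 lists thus rest on line 23095, whose wildtypes lay apart on both. Without 23095 wildtype replicate 1, her7, mespaa and tbx16 were not called (adjusted p = 0.112, 0.112 and 0.169). The call of tbx16 was also lost without 23095 mutant replicate 4 or wildtype replicate 2 (0.0583 and 0.0965), 36433 mutant replicate 1 or 3 (0.0748 and 0.0876) and 36433 wildtype replicate 2 or 3 (0.0519 and 0.0626), and MLPH lost its call in 6 of 11 fits that left out 1 library.

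Of the other lists that passed the test in the average, Lsd1 partners had a median of 0.28 (3 rose and 1, kdm1a itself, fell of 16). The 3 that rose, GFI1, gfi1aa and GFI1B, also stand in the blood stem list, and GFI1 was matched to both lists after its value had been seen. The cilia list had a median of 0.18 (none called of 22). Yolk syncytial layer and liver had -0.58 (2 fell of 26), skeletal muscle -0.32 (1 fell of 42), epidermis -0.26 (1 fell of 32), neuronal genes -0.21 (none called of 44), ionocytes -0.36 (2 fell of 10) and fin fold -0.18 (1 fell of 21). Adjusted over the list alone, 7 rose and 2 fell among Lsd1 partners, none in cilia, 11 fell in yolk, 3 rose and 8 fell in muscle, 1 fell in epidermis, 7 fell among neuronal genes, 3 fell among ionocytes, and 1 rose and 4 fell in fin fold. With an estimated correlation these 8 lists gave an adjusted p = 0.2 for Lsd1 partners and 0.5 to 0.68 for the others. The lists of hox genes (median 0.11), interferon response (0.08), p53 targets (0.06), germ cells (0.22), heart (0.04), head (0.09), hatching gland (0.27), pronephros (0.04), neural progenitors (0), notochord (-0.02), cell cycle (-0.02) and hypoxia and glycolysis (-0.16) did not pass (adjusted p = 0.059 to 0.96). The thrombocyte list had 3 tested members, too few for the test (median 0.17). For heart both median and mean were above 0 and the test pointed down. Median, mean and test also differed in sign, without passing, for p53 targets, hypoxia and hatching gland in line 36433 and for heart, germ cells, hatching gland and neural progenitors in line 23095. Without 36433 wildtype replicate 2, 23095 wildtype replicate 1 or 36433 wildtype replicate 1, the calls of epidermis, ionocytes and neuronal genes were lost (adjusted p = 0.11, 0.068 and 0.17), and those of cilia and fin fold were lost in 3 and 5 such fits (up to 0.083 and 0.17).

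The average count depended on single libraries. It was 291 without 23095 mutant replicate 4, 56 and 196 without 23095 wildtype replicate 1 and 2, 192, 263 and 135 without 36433 mutant replicate 1, 2 and 3, and 1439, 256 and 218 without 36433 wildtype replicate 1, 2 and 3. GFI1, vwf, SASH3, gfi1aa, snai3, snai1b, spi2, gfral, EPX, muc5.1 and pnp4a kept their calls in all 11 of these fits. With library totals alone, 390 genes rose and 182 fell, so that the share of rises was 68.2% rather than 55.8%.

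**Figure D3:**
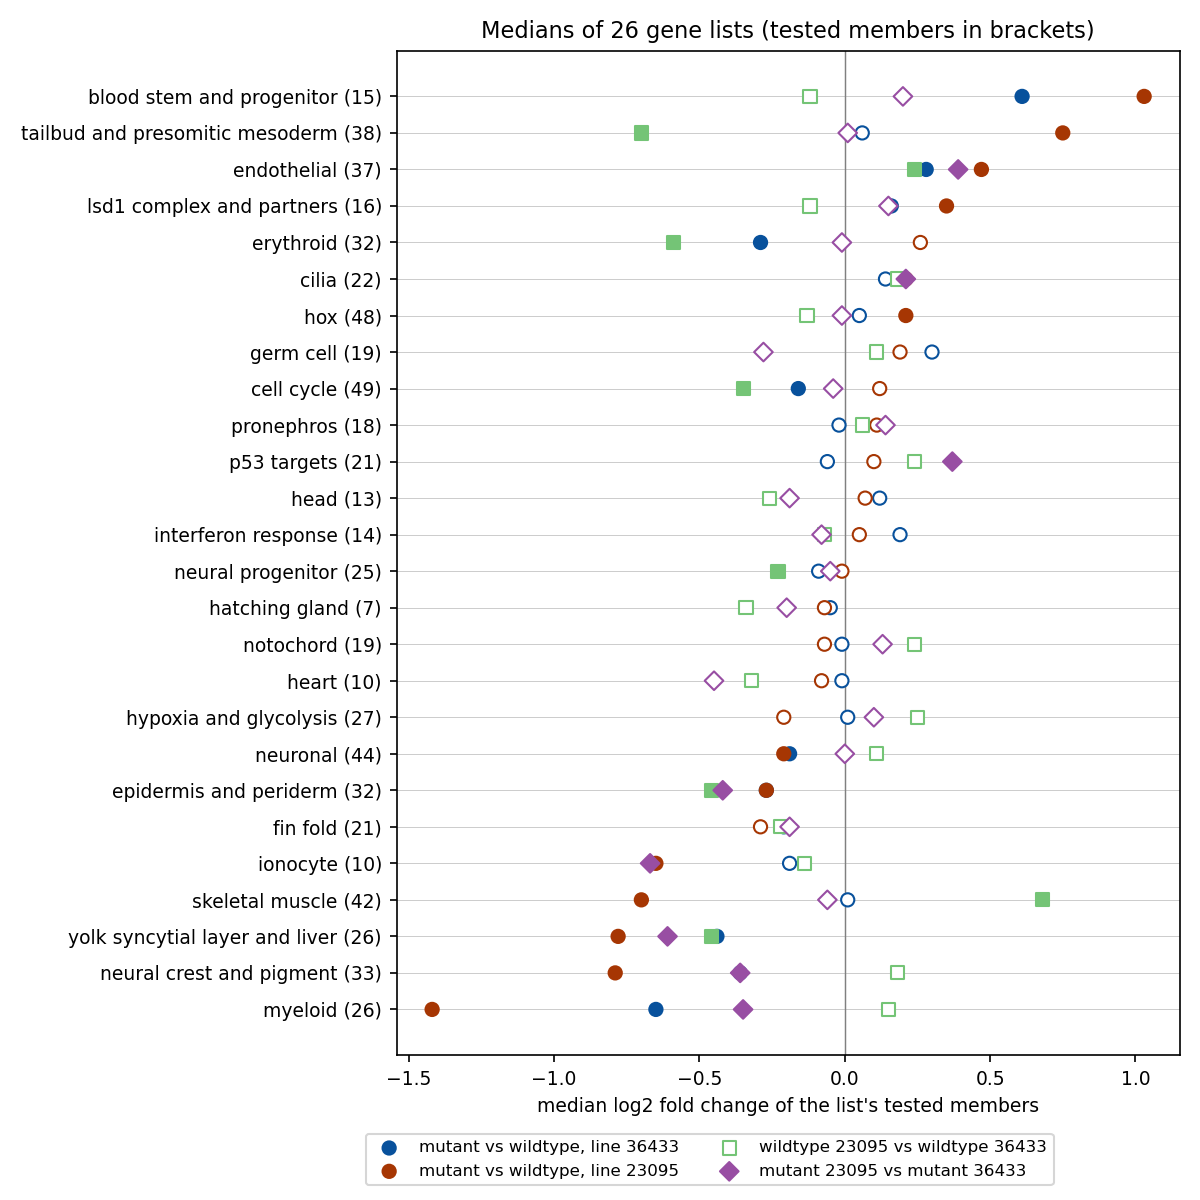
Median log2 fold change of the tested members of 26 gene lists in 4 comparisons; a filled symbol passed camera with a preset correlation, and none of them passed with an estimated one. Blood stem genes lie to the right and myeloid genes to the left in both lines, and the green squares for tailbud and muscle lie opposite to the brown points of line 23095.

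Whether the mutant effect differed between the lines was tested directly. Only kdm1a and actn2b passed (edgeR's quasi-likelihood test with Benjamini-Hochberg), with 1586 genes at an unadjusted p under 0.05. In line 36433, actn2b (ENSDARG00000071090) fell from 32.9 ± 12.5 to 3.99 ± 0.968 CPM (SD, n = 3 each). In line 23095, it was at 61.4 ± 8.68 CPM in the wildtypes (SD, n = 2) and 64.6 ± 12.6 CPM in the mutants (SD, n = 3). The effects differed by 3.12 on the log2 scale (standard error 0.40, adjusted p = 0.0286). This call was lost without 23095 mutant replicate 2 (adjusted p = 0.0603), 23095 wildtype replicate 1 or 2 (0.252 and 0.139), 36433 mutant replicate 1, 2 or 3 (0.165, 0.146 and 0.057) and 36433 wildtype replicate 2 (0.06). Only 12.5% of genes that differed by a fold of 2 were recovered by this comparison on simulated data. The count was 4 without 23095 mutant replicate 1 or 23095 wildtype replicate 2, 0 without 23095 wildtype replicate 1, and 1 without 23095 mutant replicate 2, any 36433 mutant or 36433 wildtype replicate 2. DESeq2 on all 11 libraries called 57.

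The wildtypes of the lines were compared to measure the difference between lines without a mutation, and the mutants likewise. The cardiac-type actin gene actc1c was higher in line 23095 in both, at 384 ± 214 against 1.78 ± 0.133 CPM in the wildtypes (SD, n = 2 and 3; log2 difference 7.75, standard error 0.46) and 340 ± 154 against 1.32 ± 0.114 CPM in the mutants (SD, n = 3 each; 8.01). SLC24A4, an ion exchanger, was higher in line 23095 by 5.06 between wildtypes and 4.44 between mutants. Between wildtypes, the stereocilin gene strc was higher by 3.70, and ptpdc1b and TMEM151B were lower (-4.74 and -2.35). Between mutants, actn2b was higher by 4.02, and jac1 and GGACT were lower (-6.03 and -5.93). The call of TMEM151B was lost without 23095 wildtype replicate 1 or 2 (adjusted p = 0.112 and 0.0973). That of jac1 was lost without any 23095 mutant (0.0546, 0.0502 and 0.0809 for replicates 1, 2 and 4) and without 36433 mutant replicate 1 (0.0631). That of GGACT was lost without 23095 mutant replicate 1 or 4 (0.0634 and 0.0809) and 36433 mutant replicate 1 or 3 (0.0727 and 0.06), and its difference was -9.98 without 23095 mutant replicate 2. Of the p53 targets, mdm2, which restrains p53, was called in both (1.43 and 1.21), and the list's median was 0.24 between wildtypes (adjusted p = 0.058) and 0.37 between mutants (adjusted p = 0.0007; adjusted p = 0.58 with an estimated correlation). Copies of the signal recognition particle RNA (Metazoa_SRP) also differed, but 68 identifiers share that symbol.

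In all, 53 genes were higher and 29 lower in the 23095 wildtypes than in the 36433 wildtypes, and 102 were higher and 133 lower in the 23095 mutants than in the 36433 mutants (edgeR's quasi-likelihood test with Benjamini-Hochberg). Between wildtypes the lists of muscle (0.68), endothelium (0.24), tailbud (-0.70), cell cycle (-0.35), epidermis (-0.46), erythroid cells (-0.59), yolk (-0.46) and neural progenitors (-0.23) passed the test, and with an estimated correlation gave an adjusted p = 0.34 to 0.7. None of their members was called over all genes. Adjusted over the list alone, 14 were higher in muscle, 1 higher and 14 lower in tailbud, and 1 higher and 2 lower among erythroid genes. Between mutants, muscle (-0.06) and tailbud (0.01) did not pass, and yolk (-0.61), ionocytes (-0.67), epidermis (-0.42), endothelium (0.39), cilia (0.21), neural crest and pigment (-0.36) and myeloid genes (-0.35) did, with an adjusted p = 0.58 to 0.6 with an estimated correlation. Over all genes, 3 yolk, 1 ionocyte and 1 pigment member were lower, and 1 endothelial member was higher. Adjusted over the list alone, 9 yolk, 4 myeloid, 3 ionocyte, 1 epidermis and 1 pigment member were lower, and 10 endothelial members were higher. The wildtype count was 21 and 25 without 23095 wildtype replicate 1 and 2, 301 and 26 without 36433 wildtype replicate 1 and 2, and with library totals alone 57 were higher and 51 lower, a share of 52.8% rather than 64.6%. The mutant count was 110 without 23095 mutant replicate 4 and 68, 65 and 117 without 36433 mutant replicate 1, 2 and 3.

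The authors' tables for the matching comparisons gave 122 genes at their adjusted p under 0.05 in line 36433, 968 in line 23095, 548 between wildtypes and 555 between mutants. They contained 35 of the 35, 339 of the 340, 82 of the 82 and 233 of the 235 genes called here. The name of the table for the wildtypes gives line 23095 with an extra digit, and it was read as that line.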

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

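The tests on tailbud and muscle genes in line 23095, on erythroid genes and on the whole of kdm1a's chromosome were chosen only after the result was seen.

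The mutant effect on tailbud and muscle genes differed between the lines. It was -0.81 in line 23095 minus line 36433 for skeletal muscle and 0.69 for tailbud (adjusted p = 7.2e-10 and 1.6e-08; adjusted p = 0.59 with an estimated correlation for both). A lower share of muscle tissue in the 23095 mutant pools would raise tailbud genes no more than those of neurons, notochord and epidermis. Tailbud exceeded these by 1.09 on the log2 scale (standard error 0.25), which a lower muscle share alone would not give. The tailbud list was taken up because it rose here, which favours a large gap. The tailbud mean minus theirs was -3.23 and -2.65 in the 23095 wildtypes and -2.17 to -1.49 in the 23095 mutants. It was -2.42 to -1.86 in line 36433, so the 23095 wildtypes were the ones apart. The 23095 wildtypes lay -0.70 from the 36433 wildtypes on the tailbud median (-0.87 to -0.55 when 1 library was left out), whereas the mutants lay 0.01 apart (-0.13 to 0.08), which is consistent with wildtype pools of line 23095 that stood apart, as by stage or dissection. A difference between the lines in wildtypes that the mutation removed stays open and untested, since only 2 such pools were sequenced.

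The mutant effects on kdm1a and actn2b differed between the lines by 2.2 and 3.12 on the log2 scale. Sequence inherited with the lsd1 allele could change a gene near it, and actn2b lies on kdm1a's chromosome with 124 placed genes between them. Placed genes are tested genes whose unique symbol was found in RefSeq (13900 beside kdm1a). Distances and windows here count these alone, so more genes may lie between. None of the 26 placed genes called in line 36433 was among the 200 nearest to kdm1a (one-sided Fisher's exact test, p = 1), against 5 of 241 in line 23095 (p = 0.267) and 9 of 332 in the average (p = 0.051), but actn2b itself lies outside that window, so linkage over a longer distance stays open. With actn2b, which prompted this test, left out, 3 of 25 lay on the whole chromosome where 0.957 would by chance (one-sided Fisher's exact test, p = 0.0687), 7 of 241 in line 23095 where 9.22 would (p = 0.821) and 20 of 331 in the average, the same 3 included, where 12.7 would (p = 0.0299), and SMOC1, 1 of the 3, rose in line 23095 too. Linked sequence and an effect of the allele on actn2b cannot be told apart, since no sequence was available.

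Myeloid genes fell in the average, and their mutant effect differed between the lines by -0.57 (adjusted p = 0.0019; adjusted p = 0.68 with an estimated correlation; adjusted p = 0.13 without 36433 wildtype replicate 1). Fewer blood cells of every kind would lower erythroid genes alike. In line 23095 their median was 0.26 (-0.3 to 0.96 when 1 library was left out) against -1.42 for myeloid genes (-1.71 to -1.26), so they did not fall alike. That value rests on 2 wildtype pools with erythroid means of 3.65 and 4.90 log2 CPM. These wildtypes also lay -0.59 from the 36433 wildtypes on the erythroid median, so a loss of all blood cells was not excluded. It stays open in line 36433 too, where the medians were -0.29 (-0.55 to -0.15) and -0.65 (-0.85 to -0.4). With the yolk level of each library as a covariate the myeloid median was -0.67 (-0.96 to -0.58), from -1.04 without it, which argues against yolk as the whole cause and leaves a part open. Without the shallow library, 23095 mutant replicate 2, 7 of the 9 myeloid genes were still lower. Fewer myeloid cells, or less expression in each, may remain as hypotheses, and neither was tested.

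The mutant effect also differed between the lines for cell cycle (0.26, adjusted p = 1.5e-06), neural crest and pigment (-0.52, adjusted p = 0.0002), erythroid cells (0.46, adjusted p = 0.0019), yolk syncytial layer and liver (-0.39, adjusted p = 0.018), Lsd1 partners (0.17, adjusted p = 0.021), ionocytes (-0.58, adjusted p = 0.021), endothelium (0.13, adjusted p = 0.026) and blood stem cells (0.41, adjusted p = 0.026). With an estimated correlation these 8 gave an adjusted p = 0.59 to 0.81. The list of Lsd1 partners includes kdm1a itself, the only 1 of its 16 members whose difference was called. For cell cycle and erythroid cells the wildtypes of the lines lay -0.35 and -0.59 apart and the mutants -0.04 and -0.01, as for tailbud and muscle, so whether the mutants or the wildtype pools of line 23095 made these differences stays open. The 2 wildtype pools of line 23095 had erythroid means of 3.65 and 4.90 log2 CPM. Cell cycle and neural crest kept their calls without any 1 library; the other 6 lost theirs in 3 to 5 such fits (adjusted p up to 0.79, 0.63, 0.23, 0.51, 0.34 and 0.55 in the order given).

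The authors deposited 2 comparisons that cross line and genotype, which no comparison above uses. At their adjusted p under 0.05, 23095 mutants against 36433 wildtypes gave 2325 genes and 23095 wildtypes against 36433 mutants gave 667, beside 548 between the wildtypes of the lines, from a table whose name gives line 23095 with an extra digit.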

How the results depend on the processing

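The newer quasi-likelihood method and lists matched by symbol only were chosen after the data had been seen. DESeq2's size factors, library totals and both other filters kept all 7 counts of genes within 1.5-fold. DESeq2 gave more: 124 genes in line 36433, 968 in line 23095, 1083 in the average, 57 in the difference, 569 between wildtypes, 602 between mutants and 61 shared; the cause was not tested. A fit of only the groups compared gave 32 in line 36433, 6 in line 23095 and 52 between wildtypes. Each of these fits had fewer libraries to estimate the spread, and why the count of line 23095 fell furthest was not tested. Pearson's r of log2 CPM between replicates was 0.957 to 0.973 in the 23095 mutants and 0.980 to 0.982 in the 36433 mutants. It was 0.977 in the 23095 wildtypes and 0.965 to 0.978 in the 36433 wildtypes. The newer method gave 132 between wildtypes. With the replicate number as a block, the counts were 31 in line 36433, 33 in line 23095, 211 in the average, 1 in the difference, 64 between mutants and 10 shared. The cause was not tested. Whether the numbers pair samples stayed open. Deviations from the group means were correlated between mutant and wildtype libraries of 1 number. The correlations were 0.2, 0.08 and 0.018 in line 36433 and -0.078 and -0.18 in line 23095. In line 36433, mutants 1 and 3 correlated best with the wildtype of their own number, and mutant 2 with wildtype 3. With 2 wildtypes in line 23095, the deviations of these are mirror images, so that check says little.

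Leaving out 1 library gave 12 to 64 genes in line 36433, 4 to 466 in line 23095, 56 to 1439 in the average, 0 to 4 in the difference, 21 to 301 between wildtypes, 65 to 177 between mutants and 4 to 36 shared. For kdm1a in line 23095, where no change was called, the log2 fold change ran from -0.03 to 0.21, and its sign turned. For the difference between lines in erythroid genes, the adjusted p ran from 4.3e-12 to 0.79, and the direction turned in the fit that gave 0.79. Without 1 library, 90 of 132 named results lost their call at least once, and 22 of 47 list calls did; the cause was not tested. The other settings kept 130 to 132 of the 132, except the block (82) and the fit of only the groups compared (37 of 84). An estimated correlation ended all 47 list calls, fry kept 12, matching by symbol only kept 40, library totals 45 and the block 38. The 47 are the list calls within each line, in the average and in the difference. Those between wildtypes and between mutants are not among them. At a fold of 2, 43.8% of changed genes were recovered in line 23095 on simulated data. The simulated libraries had the depths of the real ones, and other depths were not tried.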

Other observations

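Single genes of lists that did not pass as a whole were called in the average. The glycolytic enzyme gene HK2 rose by 0.84 on the log2 scale (standard error 0.15), the mitophagy receptor BNIP3 by 1.31 (standard error 0.29) and the antiviral ubiquitin ligase trim25 by 0.97 (standard error 0.16). The proteoglycan gene epyc fell by 1.38, and CUBN, an endocytic receptor of the pronephros, by 0.75. HK2 and trim25 lost their calls in 2 of 11 fits that left out 1 library, BNIP3 in 8, epyc in 7 and CUBN in 6.

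Several genes of the epidermis, fin fold, ionocytes and yolk fell in the average. The keratin krt91 fell by 0.97, the actinodin gene and1 of the fin fold by 1.85, and the ionocyte genes ca2 and slc12a10.2 by 0.60 and 2.37. Of yolk and liver genes, RBP4 and apoc2, which carry vitamin A and serve lipid transport, fell by 0.98 and 1.07. These calls were lost in 6, 8, 6, 8, 3 and 8 of 11 fits that left out 1 library.

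The labels were exchanged among libraries to see how often another split gave as many genes, and these tests were planned. For line 36433, 1 of 10 splits did, the real one (35 genes, highest other 0), and for the mutants of both lines likewise 1 of 10 (235, highest other 0); 10 splits are too few for a share under 0.05. For the average, 2 of 100 splits gave 486 genes or more, the real one and another with 881. These 100 were the real split and a random sample of the others. The share lay under 0.05, but a split with exchanged labels gave more genes than the real one, so chance was not excluded. The split with 881 exchanges 36433 mutant replicate 2 and 36433 wildtype replicate 1, which points to a structure among these samples. A swap of those labels does not match kdm1a, at 34.2 and 162 CPM in them, or GFI1, at 20 and 0.513 CPM. The mean of myeloid genes in 36433 wildtype replicate 1 was 0.84 log2 CPM, against 1.21 and 1.79 in the other wildtypes of that line.

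In a principal component analysis the first 3 components held 28.8%, 17.8% and 12.8% of the variance. On the first, 36433 wildtype replicate 1 lay at 17.2, nearer the mutants of its line (20.7, 26.1 and 9) than wildtype replicates 2 and 3 (49.4 and 48.3). On the second, 23095 wildtype replicates 1 and 2 lay at -64.1 and -44.5, and the other 9 libraries at -15.3 to 35.0. The shallow library, 23095 mutant replicate 2, lay at -57.0 on the third component.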
